A study of Drosophila melanogaster with 3 samples.

How the data were processed

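Whole Drosophila melanogaster embryos without CrebA protein were dissociated and profiled with 10x Genomics 3' single-cell RNA sequencing, per the labels. There were 3 libraries, 2 of stage 10-12 and 1 of stage 13-16. The deposited values are UMI counts per gene and cell barcode, made with Cell Ranger 6.1.2, per the file headers and the submitters' processing notes. Seurat is also named in those notes, with no step given. The genome build and annotation release are not given in the sources used here, so no coordinates were used. The matrices hold 17875 gene IDs, of which 17799 have a symbol in the gene name table; IDs without a symbol hold 0.244%, 0.221% and 0.205% of UMIs in stage 10-12 replicates 1 and 2 and stage 13-16. Throughout, libraries are listed in that order.

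Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs in 38 mitochondrial genes. Of 75923 barcodes, the mitochondrial limit removed 1201, 2291 and 6320 (8.75%, 8.78% and 17.5%), and the other limits removed 0. Median genes per barcode were 708, 1698 and 1397 and median mitochondrial shares 4.26%, 6.11% and 8.04%. Retained cells held 121176778, 348465714 and 277762958 UMIs. Doublets were scored with the Scrublet method in scanpy 1.11.5 (scikit-image 0.26.0) at an expected rate of 0.06, but its automatic threshold marked 0 barcodes in each library, so it removed none. UMI floors of 5000, 10000 and 8000, placed between the low and the high group of barcodes, were chosen after seeing the data and serve only in checks and in the naming rule below.

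Retained cells of all libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9 in Python 3.11.15, on 2000 variable genes, 40 components and 15 neighbours at resolution 2 with 2 Leiden iterations. Clusters of at least 60 cells were split again at resolution 1 on 1000 genes, 20 components and 10 neighbours. CrebA and the machinery genes were kept out of the clustering genes, and the other lists were not. A cluster took the name of the class, among 22 with 152 markers, with most markers raised, given at least 3 markers raised at a log2 fold of 1 with an offset of 10 CPM and detected in 10% of cells. After a first clustering had been inspected, 2 rules were added: the first marker of any class among the top 10 genes must belong to the class named, and a cluster with under 50% of its cells above the UMI floor stays unnamed. The second rule kept 88 clusters unnamed. The share of would-be class cells it removed was 0%, 0% and 85.6% for salivary gland-like, 31.5%, 0% and 60.3% for trachea-like, 52.2%, 71.9% and 63.7% for epidermis-like, 87.5%, 78.0% and 25% for amnioserosa-like, 5.56%, 22.6% and 27.4% for fat body-like, 64.3%, 65.6% and 22.7% for plasmatocyte-like, 51.4%, 97.5% and 76.5% for neuron-like, 14.3%, 3.69% and 14.5% for somatic muscle-like, 96.5%, 46.4% and 78.7% for germ cell-like, and 0% throughout for midgut-like cells.

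Gene lists were fixed before the data were seen: 15 lists with 357 members, of which 356 matched a gene ID, 4 of them by a synonym. The 6 machinery lists are ER translocation, N-glycosylation, ER folding and stress, COPII and ER exit, COPI and retrieval, and Golgi tethers and SNAREs, with 129 of 130 members measured. The other 9 are basement membrane, cuticle and apical matrix, cell cycle, neuronal function, muscle contraction, early patterning, heat shock and dissociation stress, cell death, and integrated stress and amino acid supply.

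UMI counts were summed per library over all retained cells, per class, or per class and remainder. Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, adjusted p under 0.05 by Benjamini-Hochberg) in R 4.3.3, and with DESeq2 1.42.0 as the other tool. TMM factors of the whole-embryo fit were 1.06, 0.910 and 1.03. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. With an estimated correlation camera tests on the residual degrees of freedom, 1 between stages and few between classes. Almost no list could pass there at any correlation. A call lost in that setting therefore does not show that correlation between genes explains it. Stage was tested within classes of at least 50 cells in each library; salivary gland-like, amnioserosa-like, fat body-like, plasmatocyte-like and neuron-like cells fell short. Classes were tested against all other retained cells with the library as a block. A profile needed at least 5 cells, a limit set after seeing the data, since a limit of 10 would drop germ cell-like cells. The use of the 6 machinery lists as 1 set, and adjustment over 10 classes and over 60 class and list pairs, were also set after seeing the data. Nothing in the labels says that the replicates came from separate embryo collections, so p-values measure at most the spread between these libraries, moderated across genes by edgeR. In plasmatocyte-like, fat body-like and amnioserosa-like cells the p-values of single genes follow a normal curve. Small p-values there do not measure a gene's own spread between libraries.

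Named genes follow a rule fixed beforehand: CrebA, Xbp1, sage and fkh always; the 12 highest and 12 lowest log2 fold changes between stages at a mean of at least 20 CPM and beyond both stage 10-12 libraries, without CG or CR numbers and noncoding genes, ranked without the test when under 5 genes pass it; up to 4 members per list; and the 5 largest rises and 3 largest falls of machinery genes per class. Tb, with 0 CPM in 1 stage 10-12 library, has no usable fold change and is not described. E(spl)m5-HLH was named after its value was seen.

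Counts were simulated with 100 genes changed at each size, at dispersions already moderated across genes, so recovery in the data may be lower. On them the whole-embryo stage test recovered 1 gene at 2-fold and 57 at 4-fold, with 14 false calls among 13016 unchanged genes. Within epidermis-like cells it recovered 0 and 16, for salivary gland-like cells against the remainder 52 and 99, and for fat body-like cells 48 and 99. Alternatives tried were RLE factors, no count filter, DESeq2, an estimated correlation, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, libraries thinned to the smallest total, each library left out, resolution 1 and 3, each library clustered alone, machinery genes used to cluster, equal weight for each other named class, and no library block. Added after seeing the data were the UMI floors as a filter, the top 6% of doublet scores above the floors left out (228, 574 and 607 barcodes), low-depth clusters named too, and resolution 3 for stage within classes.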

Results

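RNA was counted in single cells of whole Drosophila melanogaster embryos that make no CrebA protein. CrebA is a bZIP transcription factor of the CREB3 family, known for driving secretory pathway genes in embryonic glands and epithelia. Per the labels, embryos were obtained from 2 CrebA mutant alleles carried over a balancer chromosome marked with twist-driven GFP, and embryos without GFP were sorted out for dissociation. Stage 10-12, the early part of organ formation, is represented by 2 replicate libraries, and stage 13-16, the late part, by 1 library. The stage 13-16 library carries the same batch tag as stage 10-12 replicate 1, so values of the stage comparisons against that replicate alone are given beside the pooled ones. Embryos with CrebA protein were not analysed here, and none of the values below measures the effect of losing it.

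The deposited matrices held 13726 barcodes with 125321742 UMIs in stage 10-12 replicate 1, 26105 barcodes with 367993130 UMIs in replicate 2, and 36092 barcodes with 309406071 UMIs at stage 13-16. Median depth was 1616, 6480 and 4804 UMIs per barcode in the same order. Each library had a large group of barcodes at low UMI counts and a smaller one at high counts, and 70.6%, 61.0% and 70.7% of barcodes lay below a floor placed between the groups. Whether the barcodes of the low group are whole cells or debris is not known; those past the filter stay among the retained cells, and so in the sums and in the remainder used below. After removal of barcodes with over 10% mitochondrial UMIs, 12525, 23814 and 29772 barcodes remained. The chi-square of the UMI counts of the stage 10-12 replicates was 743 per degree of freedom. It sets them against counting error alone, which separate libraries of this depth would exceed anyway, so it shows only that the 2 matrices do not hold the same counts. Across genes, Pearson's r of log2(CPM + 1) was 0.984 between the stage 10-12 replicates, 0.969 between replicate 1 and stage 13-16, and 0.935 between replicate 2 and stage 13-16; genes are not independent replicates.

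**Figure D1:**
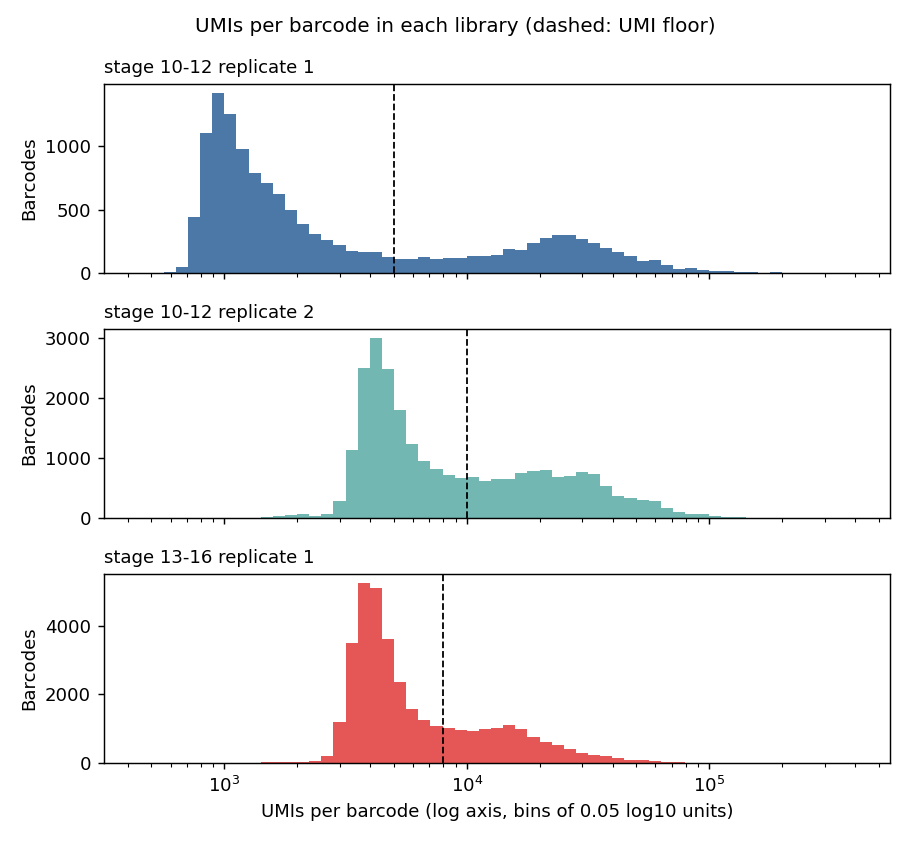
Number of barcodes by UMIs per barcode (log axis) in each library, with the UMI floor of 5000, 10000 and 8000 UMIs drawn as a dashed line. In all 3 libraries the larger group of barcodes lies below the floor.

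RNA from the CrebA gene itself (FBgn0004396) was present in every library, at 115.3 CPM in stage 10-12 replicate 1, 66.6 CPM in replicate 2 and 90.4 CPM at stage 13-16. The alleles are described as lacking protein, and RNA tagged at its 3' end does not test that description. Between the stages CrebA RNA differed by a log2 fold change of -0.05 (SE 0.37). Xbp1 (FBgn0021872), a transcription factor of the unfolded protein response, stood at 104 ± 39.2 CPM (SD, n = 2) at stage 10-12 and 154 CPM at stage 13-16. The salivary gland factors sage (FBgn0037672) and fkh (FBgn0000659) stood at 8.35 ± 2.49 and 125 ± 14.9 CPM at stage 10-12 (SD, n = 2), against 5.39 and 67.3 CPM at stage 13-16. The log2 fold changes of CrebA, Xbp1, sage and fkh against replicate 1 alone were -0.29, 0.29, -0.84 and -0.70. None of these 4 genes passed the test between stages.

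The first comparison asks how the transcriptome of embryos without CrebA protein moved from stage 10-12 to stage 13-16, over all retained cells of each library. Of the 12 genes with the highest log2 fold changes, TpnC47D, up and Mhc are on the muscle contraction list and Gasp is on the cuticle list, while the other 8 are on none of the lists fixed beforehand. Osi14 (9.21, SE 1.24), Osi7 (7.19, SE 1.71), Osi6 (6.80, SE 2.21) and Osi15 (6.77, SE 0.40) belong to the Osiris family of insect membrane proteins, and Gasp (4.79, SE 0.42) encodes a chitin-binding protein of the tracheal lining. TpnC47D (5.05, SE 1.12) encodes a troponin C, up (4.82, SE 1.06) troponin T and Mhc (4.75, SE 0.93) muscle myosin heavy chain. The metallothionein gene MtnA stood at 6.85 ± 4.35 CPM at stage 10-12 (SD, n = 2) and at 212 CPM at stage 13-16. The other genes among the 12 with the highest fold changes were ect, spz6 and ImpL1, at 6.62, 5.03 and 4.90. Against replicate 1 alone the fold changes were 8.27 for Osi14, 6.26 for Osi7, 5.83 for Osi6, 6.90 for Osi15, 5.73 for ect, 4.27 for TpnC47D, 4.34 for spz6, 4.48 for MtnA, 4.08 for ImpL1, 4.06 for up, 5.11 for Gasp and 4.05 for Mhc. Against replicate 2 alone they were 11.17 for Osi14, 10.61 for Osi7, 12.15 for Osi6, 6.68 for Osi15, 9.42 for ect, 7.01 for TpnC47D, 6.45 for spz6, 5.63 for MtnA, 7.06 for ImpL1, 6.64 for up, 4.54 for Gasp and 6.23 for Mhc.

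Of the 12 genes with the lowest log2 fold changes, l(1)sc, ac and gsb are on the early patterning list. The proneural genes l(1)sc and ac had log2 fold changes of -3.29 (SE 0.75) and -3.02 (SE 0.75). The scabrous gene sca, a regulator of proneural clusters, stood at -3.11, and bib, a neurogenic channel gene, at -2.77. BobA and Brd, Bearded-family antagonists of Notch signalling, stood at -2.68 and -2.52, the heart and mesoderm homeobox gene tin at -2.87 and the segment polarity gene gsb at -2.52. The scavenger receptor gene Sr-CII had the lowest value, at -3.38 (SE 1.19). Septin5, Cks30A and jeb followed at -2.95, -2.75 and -2.50. Replicate 2 weighed on most of these values: against replicate 1 alone they were -1.70 for Sr-CII, -2.44 for l(1)sc, -2.08 for sca, -2.21 for ac, -1.63 for Septin5, -1.51 for tin, -2.01 for bib, -1.99 for Cks30A, -1.87 for BobA, -1.72 for Brd, -2.04 for gsb and -1.77 for jeb. Against replicate 2 they were -4.13 for Sr-CII, -3.82 for l(1)sc, -3.70 for sca, -3.52 for ac, -3.62 for Septin5, -3.55 for tin, -3.26 for bib, -3.24 for Cks30A, -3.19 for BobA, -3.02 for Brd, -2.86 for gsb and -2.97 for jeb.

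These genes are given as values, because edgeR's quasi-likelihood test called 0 of 13350 genes higher and 0 lower at stage 13-16 after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.218. At an unadjusted p under 0.05 it counted 1831 genes higher and 671 lower, and DESeq2 called 1174 higher and 237 lower, the 24 genes named by size among them. The design leaves 1 residual degree of freedom, since the lone stage 13-16 library is assumed to vary like the stage 10-12 pair. In the whole-embryo simulation the same test recovered 1 of 100 genes changed 2-fold and 57 of 100 changed 4-fold. Simulated counts used dispersions already moderated across genes, so this recovery may be too high for the data. The 24 genes named by size, each more than 4-fold apart in the pooled fit, were not called. They were picked by fold change in these same libraries, so their size is no separate evidence of change. Against replicate 1 alone some lay under 4-fold, such as tin at a log2 fold change of -1.51. Given the low recovery of simulated 2-fold changes, 0 calls do not mean that few genes changed.

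By gene list, RNA of differentiated tissues was higher at stage 13-16 and RNA of dividing and early patterned cells was lower. Muscle contraction genes rose by a median log2 fold change of 3.22 (22 of 24 members positive), neuronal function genes by 2.90 (20 of 24), cuticle and apical matrix genes by 2.41 (46 of 51) and basement membrane genes by 1.44 (15 of 16). Cell cycle genes had a median of -1.85 with all 30 members negative, and early patterning genes a median of -1.29 with 29 of 30 negative. These 6 calls rest on camera's preset correlation and were lost with an estimated one (each adjusted p = 0.518 with an estimated correlation). That setting tests on 1 residual degree of freedom and could hardly call any list, so it does not tell whether correlation between genes explains the calls. Among single members, Col4a1 and vkg, the collagen IV chains of basement membrane, had log2 fold changes of 3.68 and 3.48, Timp and Glt 4.46 and 3.15. In the cuticle list dyl and TwdlF stood at 6.46 and 5.95, and Cpr62Bb stood at 0.0165 and 0.0172 CPM at stage 10-12 and at 3.56 CPM at stage 13-16. Vmat, Nlg2, nrv3 and Rim of the neuronal list stood at 4.43, 4.37, 4.08 and 3.94, and wupA, troponin I, at 4.70. The mitotic genes CycB3, BubR1, polo and fzy stood at -2.29, -2.25, -2.19 and -2.16. Against replicate 1 alone the values were 3.02 for Col4a1, 2.79 for vkg, 4.01 for Timp, 2.55 for Glt, 5.98 for dyl, 5.72 for TwdlF, 4.01 for Vmat, 3.73 for Nlg2, 3.78 for nrv3, 3.66 for Rim, 3.92 for wupA, -1.78 for CycB3, -1.50 for BubR1, -1.64 for polo and -1.69 for fzy. With replicate 2 as the only early library they were 4.997 for Col4a1, 4.88 for vkg, 5.12 for Timp, 4.24 for Glt, 7.14 for dyl, 6.25 for TwdlF, 5.02 for Vmat, 5.51 for Nlg2, 4.47 for nrv3, 4.30 for Rim, 6.64 for wupA, -2.66 for CycB3, -2.73 for BubR1, -2.58 for polo and -2.50 for fzy.

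The secretory machinery moved far less than these tissue programmes. Taken as 1 set over the whole embryo, it had a median of -0.21, with 95 of 129 members negative. N-glycosylation genes had a median of -0.29 (16 of 20 members negative) and COPI and retrieval genes a median of -0.42 (16 of 18 negative), and both passed the list test as lower at stage 13-16 with the preset correlation. Neither call held with an estimated correlation (adjusted p = 0.518 for both with an estimated correlation). For COPI and retrieval the estimated correlation, -0.0458, lay below the preset 0.01, so a higher correlation did not end that call. The other called lists had estimates above the preset: 0.0275 for cuticle, 0.211 for N-glycosylation and 0.522 for early patterning. Muscle contraction, neuronal function, basement membrane and cell cycle stood at 0.543, 0.590, 0.75 and 1. Their preset p-values thus assume less correlation than was estimated, though each estimate rests on 1 residual degree of freedom. ER translocation (-0.25, 17 of 22 negative) and Golgi tethers and SNAREs (-0.36, 22 of 29 negative) fell just short of the threshold. ER folding and stress (-0.08) and COPII and ER exit (-0.09) did not pass. Genes of cell death (-0.08) and of integrated stress and amino acid supply (0.43) did not pass either. Heat shock and dissociation stress genes, a sign of handling, had a median of 0.92 at stage 13-16 with 14 of 18 members positive, just short of the threshold (camera, adjusted p = 0.0530).

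The lists were compared by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 15 lists. The adjusted p was 3.10e-10 for muscle contraction, 1.32e-08 for neuronal function, 1.80e-14 for cuticle, 1.59e-05 for basement membrane, 1.94e-18 for cell cycle, 7.43e-10 for early patterning, 0.0217 for N-glycosylation and 0.0267 for COPI and retrieval, against 0.518 for each of the 8 as the adjusted p with an estimated correlation. Adjusted over the list alone, edgeR called 6 basement membrane, 16 cuticle, 14 neuronal and 14 muscle genes higher and 27 cell cycle genes lower, where the adjustment over all genes tested called 0 in each. Within the shared batch tag, against stage 10-12 replicate 1 alone, the medians of log2(CPM + 1) differences were 2.41 for muscle contraction, 1.75 for neuronal function, 1.54 for cuticle, 0.98 for basement membrane, -1.49 for cell cycle, -0.98 for early patterning, -0.27 for N-glycosylation and -0.44 for COPI and retrieval. Against replicate 2 they were 3.36, 2.60, 2.26, 2.11, -1.95, -1.28, -0.13 and -0.24.

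**Figure D2:**
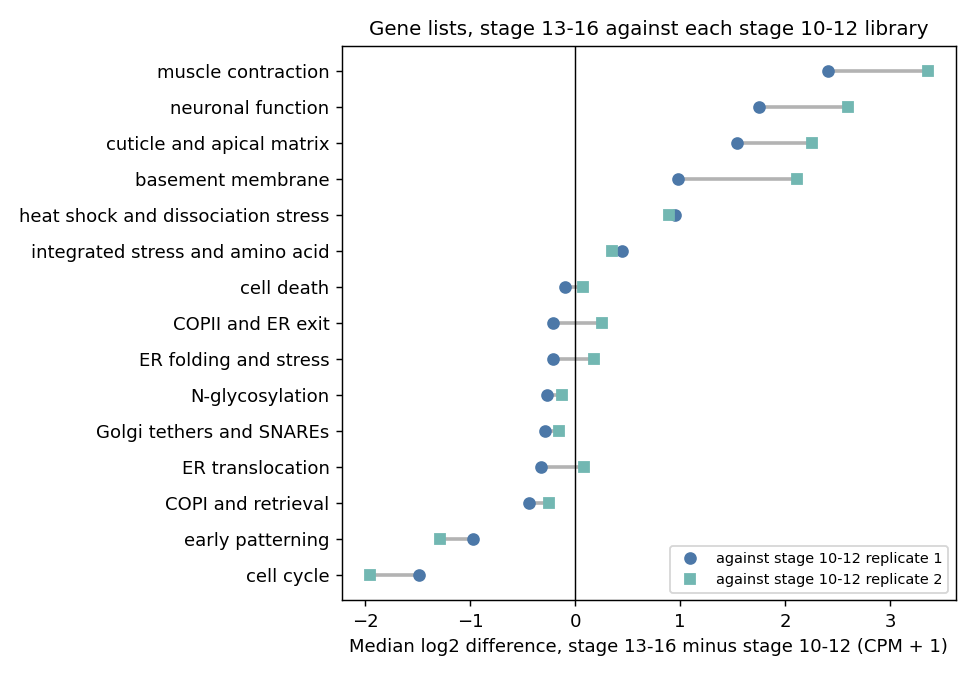
Median log2 difference of CPM + 1 between stage 13-16 and each stage 10-12 library (circles, replicate 1; squares, replicate 2) for the 15 gene lists. Muscle, neuronal, cuticle and basement membrane genes lie above 0 and cell cycle and early patterning genes below 0 against both libraries, while ER folding and stress, COPII and ER exit, ER translocation and cell death change sign between them.

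Clustering gave 582 clusters, of which 170 could be named after known markers, in 20 classes. Named cells made up 15.2% of retained cells in stage 10-12 replicate 1, 16.3% in replicate 2 and 23.0% at stage 13-16, and the classes below are cells like the named tissue rather than a full census of it. Somatic muscle-like cells were 5.45% (95% exact binomial interval 5.06 to 5.87), 2.41% (2.22 to 2.61) and 9.06% (8.74 to 9.39) of retained cells in stage 10-12 replicates 1 and 2 and stage 13-16. Fat body-like cells were 0.950%, 0.172% and 3.30%, neuron-like cells 2.43%, 0.0630% and 3.48%, and epidermis-like cells 1.67%, 2.87% and 2.09%. Salivary gland-like cells numbered 16, 34 and 16 and plasmatocyte-like cells 15, 66 and 269. Intervals cover counting error only, and a rule that leaves clusters of low depth unnamed, set after the data were seen, strongly shapes these shares: with those clusters named too, named cells were 25.2%, 29.8% and 44.5%.

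Stage was then compared inside the 3 classes of the planned set that held at least 50 cells in each library, the trachea-like, epidermis-like and somatic muscle-like cells. Cell cycle genes fell inside each of the 3, with medians of -2.21, -2.62 and -1.51 and every one of the 30 members negative (camera, adjusted p = 1.63e-13, 6.76e-16 and 4.70e-10; adjusted p = 0.618, 0.618 and 0.630 with an estimated correlation). With replicate 1 alone as the early library these medians were -1.41, -1.85 and -0.70, with 9 of the 30 members positive in somatic muscle-like cells. Cuticle genes rose in trachea-like (2.40, 24 of 25 members positive) and epidermis-like cells (3.30, 37 of 38), muscle contraction genes in somatic muscle-like cells (3.13, 21 of 23), and basement membrane genes in all 3, by 1.58, 1.82 and 1.18. None of these rises held with an estimated correlation (each adjusted p = 0.618 with an estimated correlation). Against replicate 1 alone the cuticle medians were 1.49 and 3.17, the muscle contraction median 2.62 and the basement membrane medians 1.78, 1.93 and 0.67.

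The secretory machinery, taken as 1 set, fell in somatic muscle-like cells, with a median of -0.23 and 105 of 128 members negative (camera, adjusted p = 0.000172; p = 0.111, unadjusted over the 3 classes, with an estimated correlation). It was not called in trachea-like (0.11) or epidermis-like cells (-0.05). Against replicate 1 alone the medians were -0.26, -0.04 and -0.17 in somatic muscle-like, trachea-like and epidermis-like cells. N-glycosylation genes had medians near -0.50 in all 3 classes: -0.50 in trachea-like cells (15 of 20 negative, not called), and -0.49 and -0.47 in epidermis-like and somatic muscle-like cells, where they were called lower. Neither call held (adjusted p = 0.684 and 0.618 with an estimated correlation), and against replicate 1 alone the 3 medians were -0.37, -0.43 and -0.39. ER translocation and COPI and retrieval were called lower in somatic muscle-like cells, each with a median of -0.30 (each adjusted p = 0.618 with an estimated correlation), and stood at -0.39 and -0.27 against replicate 1 alone.

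Genes of other tissues moved in the same direction inside these classes. Muscle contraction genes had medians of 3.67 in trachea-like and 3.35 in epidermis-like cells, neuronal function genes 0.98 and 3.14 there and 2.82 in somatic muscle-like cells, and cuticle genes 3.29 in somatic muscle-like cells. Heat shock genes stood higher in all 3 classes as well, by medians of 0.92, 1.49 and 1.07. All 9 were called with the preset correlation and none with an estimated one (each adjusted p = 0.618 with an estimated correlation). With replicate 1 as the only early library, muscle contraction genes stood at 4.01 in trachea-like and 3.86 in epidermis-like cells, neuronal function genes at 0.92, 3.61 and 2.38, cuticle genes at 3.41 in somatic muscle-like cells, and heat shock genes at 0.68, 1.63 and 1.09. At stage 13-16 muscle contraction genes took 0.170% of UMIs in epidermis-like cells and 0.472% in the 10% of barcodes with fewest UMIs.

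By gene, edgeR called 0 of 7503, 0 of 9134 and 0 of 9154 genes in trachea-like, epidermis-like and somatic muscle-like cells, with 872, 1508 and 1450 at an unadjusted p under 0.05. DESeq2 called 183 higher and 42 lower in trachea-like, 575 and 152 in epidermis-like, and 337 and 39 in somatic muscle-like cells. Of the machinery, edgeR and DESeq2 both called 0 genes in any of the 3 classes, and at an unadjusted p under 0.05 edgeR counted 1 higher in trachea-like cells, 0 in epidermis-like cells, and 1 higher and 3 lower in somatic muscle-like cells. Each class was spread over at least 10 clusters at either stage. The largest cluster of trachea-like cells was c21.7 at stage 10-12, with 31.3% of them there and 0.581% of those of stage 13-16, and c23.3 at stage 13-16, with 27.9% and 0.642% of those of stage 10-12. For epidermis-like cells these were c21.4 (25.3% and 0.321%) and c19.1 (25.4% and 0.560%), and for somatic muscle-like cells c8.11 (12.1% and 0%) and c22.10 (11.8% and 0.0796%).

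The last comparison asks which cells carry most secretory machinery RNA in embryos without CrebA protein. Each class was set against all other retained cells of the same library, with the library as a block, and with CrebA and the machinery genes kept out of the clustering. The remainder includes the low-UMI barcodes, which are not known to be cells, so a fold change against it is one against all retained RNA rather than against known cells. In plasmatocyte-like cells, the macrophages of the embryo, 67 of 129 machinery genes were higher and 2 lower than in the remainder, with a median log2 fold change of 0.92. By number of machinery genes called higher, fat body-like cells came next with 34 higher and 4 lower (median 0.41), then midgut-like cells with 25 and 5 (median 0.15). The midgut-like median turned below 0 with likely doublets left out. Its call as a set ended with equal weight per class, as given under the processing settings. By median in the main setting, amnioserosa-like cells (5 higher, 1 lower, median 0.54) came second and midgut-like cells lay below salivary gland-like, trachea-like and epidermis-like cells. Amnioserosa-like cells lost that place above the UMI floors, where their median fell, as given below. The number of calls over all genes also differed between classes: of the genes tested, 1285 of 10370 were higher in plasmatocyte-like, 1337 of 10532 in fat body-like and 1681 of 10334 in midgut-like cells, against 208 of 9838 in salivary gland-like and 535 of 10014 in amnioserosa-like cells. In amnioserosa-like cells machinery genes were called higher less often than all genes, and in midgut-like cells only slightly more often. edgeR moderated the spread of genes to a different degree in each class, so counts of calls are not on a common footing. Sec63 in fat body-like cells (0.69, SE 0.27) had an unadjusted p of 0.0103 by edgeR. Sec22 in trachea-like cells, with fold change and SE in like proportion (0.52, SE 0.20), had one of 0.0363. In salivary gland-like cells 4 were higher and 0 lower (median 0.23; 20 and 5 at an unadjusted p under 0.05 by edgeR; 6 and 0 by DESeq2). Trachea-like and epidermis-like cells had 1 gene higher and 2 lower each, with medians of 0.23 and 0.17. Of all genes tested, 437 were higher and 887 lower of 10490 in trachea-like cells. In epidermis-like cells 449 were higher and 633 lower of 10694. In both classes machinery genes were called less often than all genes in either direction. Neuron-like cells had 10 higher and 9 lower and somatic muscle-like cells 9 and 19, with medians of -0.10 and -0.09. Of all genes tested, 1302 were higher and 1594 lower of 10702 in neuron-like cells. In somatic muscle-like cells 1686 were higher and 2803 lower of 10752. Machinery genes were thus called less often than all genes in either direction, and the medians of all genes were -0.21 and -0.20. Germ cell-like cells lay lowest by median (-0.35) and by number of genes lower, with 3 higher and 35 lower. There 1976 of the 10223 genes tested were lower, and the median of all genes was -0.27. By share of UMIs, given below, somatic muscle-like cells lay lower than germ cell-like cells.

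In plasmatocyte-like cells ERp60, a protein disulfide isomerase, was higher by a log2 fold change of 3.05 (SE 0.31, adjusted p = 1.76e-20), and CaBP1, Hsc70-3 (the ER chaperone BiP) and prtp by 2.44, 2.21 and 2.13. Alg7, which starts the N-glycan precursor, was higher by 2.52 (SE 0.39). These 5 genes were higher in 3 of 3 libraries. Of the lists, 19 of 26 ER folding genes, 12 of 18 COPI and retrieval genes, 11 of 20 N-glycosylation genes, 8 of 14 COPII genes, 10 of 29 Golgi genes and 7 of 22 ER translocation genes were higher. Xbp1 was higher by 1.52 (SE 0.34, adjusted p = 7.75e-05). The 2 machinery genes that were lower were wbl (-1.67) and Gmap (-1.40).

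wbl, the ER protein windbeutel that dorsal patterning needs to bring the sulfotransferase Pipe out of the ER, and the golgin gene Gmap differed strongly between classes, and each was called higher in 2 of the 10. In salivary gland-like cells wbl was higher by 4.28 (SE 0.20, adjusted p = 3.54e-07) and Gmap by 2.98 (SE 0.44, adjusted p = 0.00139), with Hsc70-3 at 1.57 and sip3 at 0.93, all in 3 of 3 libraries. wbl was also higher in epidermis-like cells, by 1.71, and lower in fat body-like (-2.11), somatic muscle-like (-2.26), midgut-like (-1.77) and germ cell-like cells (-3.94). Gmap was higher in midgut-like cells, by 2.20, and lower in trachea-like (-2.02), epidermis-like (-1.86), somatic muscle-like (-2.03), fat body-like (-1.45) and neuron-like cells (-1.76).

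Fat body-like cells had higher ERp60 (1.67, SE 0.25), P58IPK (1.34), SrpRalpha (1.28), Hsc70-3 (1.27) and Sec31 (1.23), and lower cnir (-1.25). Of their lists, 11 ER folding genes, 10 ER translocation genes and 0 Golgi genes were higher (0 Golgi genes by edgeR among 34 calls; 2 Golgi genes were lower). Hsc70-3 was higher in trachea-like cells, by 1.28, and opm, of the p24 family, was lower there (-1.13) and in epidermis-like cells (-0.997). Midgut-like cells had higher Der-2 (2.16), gny (1.81), Alg9 (1.26) and xit (1.18), with Tango9 (-1.12) and Ero1L (-0.91) lower. Neuron-like cells had higher cnir (2.19), Sec16 (1.28), Rab2 (1.09), Alg9 (1.09) and Rab6 (0.89), and lower loj (-1.69) and Surf4 (-0.99). Somatic muscle-like cells had higher Trp1 (2.71, SE 0.18), Ero1L (2.26, SE 0.19), Alg12 (1.92), Bet1 (0.98) and Alg3 (0.80), and lower Tango2 (-1.24). Germ cell-like cells had lower Gp93 (-2.67) and cni (-2.51), and higher PEK (1.51), Sil1 (1.32) and Sec61gamma (0.76).

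Amnioserosa-like cells were tested in the stage 10-12 libraries alone, since stage 13-16 held 3 of them. Der-2 (2.79), Alg7 (2.13), Hsc70-3 (1.79), Atf6 (1.74) and ERp60 (1.32) were higher and wbl (-2.50) lower, with a machinery median of 0.54. Above the UMI floors that median was 0.04. This class joined 2 unlike clusters: c7.6 held 5 of the 6 replicate 1 cells, and c1.6, led by E(spl)m5-HLH and other Enhancer of split genes, held 29 of the 40 replicate 2 cells. The sign of wbl turned under 5 other settings and that of ERp60 under 2, as given under the processing settings. Above the UMI floors Der-2, Alg7 and Hsc70-3 lost their calls in this class.

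The counts come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. Adjusted over the list alone, plasmatocyte-like, fat body-like and germ cell-like cells had 75, 32 and 3 genes higher and 3, 3 and 35 lower; midgut-like cells had 7 and 2, neuron-like 6 and 2, somatic muscle-like 8 and 13, amnioserosa-like 5 and 1, salivary gland-like 3 and 0, trachea-like 0 and 1, and epidermis-like 1 and 1. DESeq2, adjusted over all genes, called 74 higher and 2 lower in plasmatocyte-like cells, 47 and 4 in fat body-like, 22 and 6 in midgut-like, 14 and 13 in neuron-like, 11 and 2 in trachea-like, 10 and 19 in somatic muscle-like, 7 and 4 in epidermis-like, 7 and 36 in germ cell-like, 6 and 0 in salivary gland-like, and 3 and 1 in amnioserosa-like cells. With camera's preset correlation the machinery as 1 set was called in 8 of 10 classes (camera, adjusted p = 1.38e-21 in plasmatocyte-like cells), the exceptions being neuron-like and somatic muscle-like cells. Of the called sets, only that of germ cell-like cells had a median below 0, at -0.35. At the same preset, 28 of 60 single lists were called. With an estimated correlation 0 of 10 and 0 of 60 were (smallest adjusted p = 0.718 for the sets and 0.820 for the lists with an estimated correlation). That setting tests on the few residual degrees of freedom of these fits and could hardly call any set. Its counts of 0 do not show that correlation between genes explains the calls. The median of all genes in these fits lay between -0.34 and -0.11, so a machinery median of 0 already lies above it. With barcodes above the UMI floors alone, a setting added after the data were seen, edgeR counted 82 higher in plasmatocyte-like and 46 in fat body-like cells, and the following counts moved by over 1.5 times: 11 higher in midgut-like cells, 14 higher and 4 lower in trachea-like, 4 higher in epidermis-like, 1 higher and 3 lower in amnioserosa-like, 19 lower in neuron-like, and 5 higher and 10 lower in somatic muscle-like cells.

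Single libraries moved several of these counts by over 1.5 times. Without stage 13-16, plasmatocyte-like cells had 42 machinery genes higher, germ cell-like cells 9 higher, salivary gland-like cells 15 higher, trachea-like cells 0 higher and somatic muscle-like cells 7 lower; 1 gene was then lower in each of salivary gland-like, trachea-like and epidermis-like cells. Without stage 10-12 replicate 1, trachea-like cells had 2 higher, epidermis-like cells 1 lower, midgut-like cells had 10 higher and 3 lower, neuron-like cells 5 and 4, and germ cell-like cells 0 higher and 17 lower. Without stage 10-12 replicate 2, trachea-like cells had 29 higher and 4 lower, epidermis-like cells 6 and 5, salivary gland-like cells 17 higher, midgut-like cells 11 higher, neuron-like cells 6 higher and 1 lower, somatic muscle-like cells 5 and 8, and germ cell-like cells 1 higher; the medians were then 0.41 in salivary gland-like, 0.29 in epidermis-like, 0.61 in fat body-like and 0.06 in midgut-like cells. Of the named genes, calls ended without 1 library for sip3 in salivary gland-like, Hsc70-3 in trachea-like, opm in both epithelial classes, cnir in fat body-like, Alg9, Surf4, loj and Gmap in neuron-like, Alg3 and Tango2 in somatic muscle-like, Ero1L and Tango9 in midgut-like, and PEK, Sil1 and Sec61gamma in germ cell-like cells. Fold changes that kept their call but moved by over 1.5 times were Der-2 in midgut-like cells, 1.30 without replicate 2, and Gmap in neuron-like cells, -2.67 without stage 13-16. Above the UMI floors, calls ended for sip3 in salivary gland-like, Alg3 and wbl in somatic muscle-like, Tango9 in midgut-like and Sec61gamma in germ cell-like cells. Other settings ended calls of named genes too, which are not listed by gene. These were 44 calls without the library block, 16 with each library clustered alone and 15 with equal weight per class, among others. The machinery as 1 set lost its call in germ cell-like cells without replicate 1 (-0.36, adjusted p = 0.0922).

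As a share of UMIs, the machinery lists took 3.46 ± 1.12% (SD, n = 2) in plasmatocyte-like cells at stage 10-12 and 3.02% (95% exact binomial interval 3.00 to 3.03) at stage 13-16. Over all retained cells the share was 1.53 ± 0.194% (SD, n = 2) and 1.41%. Salivary gland-like cells held 1.97 ± 0.527% and 1.78%, fat body-like cells 1.95 ± 0.446% and 2.00%, trachea-like cells 1.69 ± 0.401% and 1.83%, and epidermis-like cells 1.64 ± 0.351% and 1.53%. In each of the 3 libraries these 5 classes lay above the remainder, by 1.28 to 2.60 percentage points in plasmatocyte-like cells and by 0.00800 to 0.244 points in epidermis-like cells. Midgut-like cells lay above the remainder in all 3 libraries too, by 0.00162, 0.225 and 0.0264 points. Amnioserosa-like cells, the sixth class chosen for its secretion or CrebA expression, held 3.29% in replicate 1 and 1.36% in replicate 2. Midgut-like, neuron-like, germ cell-like and somatic muscle-like cells held 1.64 ± 0.0362%, 1.56 ± 0.0716%, 1.41 ± 0.0215% and 1.35 ± 0.0124% at stage 10-12, and 1.43%, 1.45%, 1.15% and 1.10% at stage 13-16. Of the named classes not tested, hindgut- and foregut-like cells held 1.72 ± 0.317% and 1.69%, above epidermis-like cells at both stages. Oenocyte-like cells held 1.71 ± 0.144% at stage 10-12 and 1.26% at stage 13-16, with 3 cells in the library with fewest. Glia-like cells, given below, lay higher, and the other untested classes lay below epidermis-like cells at stage 10-12. No p-value was computed for these shares.

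**Figure D3:**
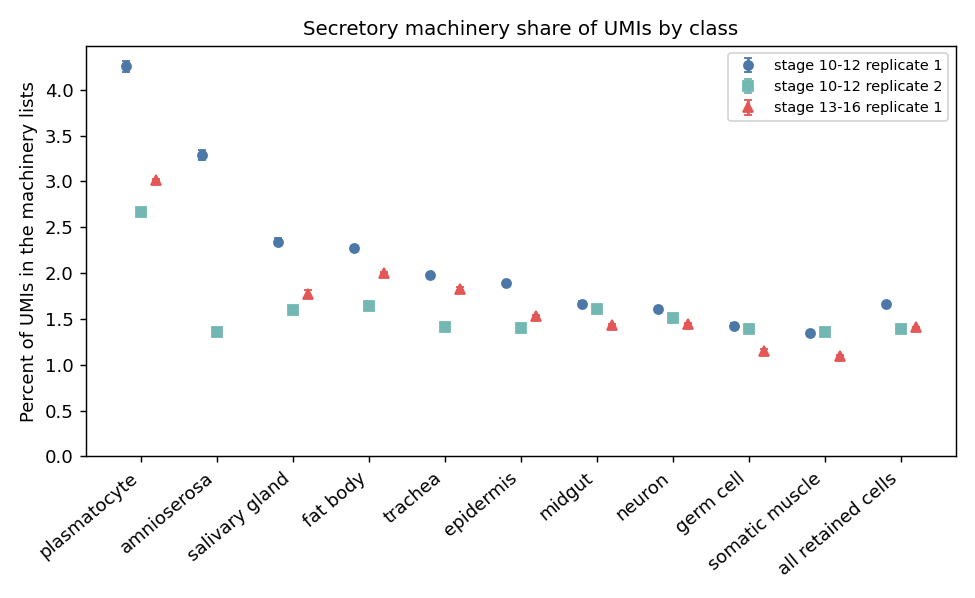
Percent of UMIs in the machinery lists by class in each library, with exact binomial intervals of 95% that cover counting error only. Plasmatocyte-like cells lie highest in all 3 libraries, from 2.67% to 4.25%, and somatic muscle-like cells range from 1.10% to 1.36%.

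CrebA RNA itself differed widely between classes. Against the remainder it was higher by a log2 fold change of 3.80 (SE 0.42) in amnioserosa-like, 3.51 (SE 0.21) in salivary gland-like, 2.18 (SE 0.34) in plasmatocyte-like, 1.24 (SE 0.26) in fat body-like, 1.13 (SE 0.23) in epidermis-like and 0.93 (SE 0.19) in trachea-like cells. It was lower in midgut-like (-0.86), neuron-like (-2.33), somatic muscle-like (-2.62) and germ cell-like cells (-3.02). All 10 passed the test, with adjusted p from 1.14e-16 to 0.0387 (edgeR), and each direction was seen in every library tested. The smallest belongs to amnioserosa-like cells, tested in 2 libraries with 6 and 40 cells from 2 unlike clusters, at 1951 and 632 CPM. As in plasmatocyte-like and fat body-like cells, p-values there follow a normal curve and do not measure the gene's own spread between libraries. Without 1 library the call ended in epidermis-like (1.07, adjusted p = 0.0794, without stage 10-12 replicate 1), midgut-like (-0.61, adjusted p = 0.144, without the same library), neuron-like (-2.13, adjusted p = 0.0530, without replicate 2) and trachea-like cells (0.86, adjusted p = 0.0518, without stage 13-16). At stage 13-16 CrebA stood at 798 CPM (95% exact Poisson interval 718 to 885) in salivary gland-like cells, where it was 1106 ± 624 CPM at stage 10-12 (SD, n = 2), and at 24.4 CPM (22.9 to 25.9) in somatic muscle-like cells. The 2 salivary gland-like values come largely from different clusters: 78% of the 50 early cells were in c21.18, which held 0% of the late ones, and all 16 late cells were in c35.0. The depth rule also left 85.6% of the would-be salivary gland-like cells of stage 13-16 unnamed. Xbp1 was also higher in amnioserosa-like (1.54) and fat body-like cells (0.75) and was not called in the other classes apart from plasmatocyte-like cells. fkh was higher in midgut-like cells (0.64) and lower in somatic muscle-like (-2.57), fat body-like (-2.24), plasmatocyte-like (-2.29), trachea-like (-2.29), epidermis-like (-1.23), germ cell-like (-4.19) and amnioserosa-like cells (-3.17); in salivary gland-like cells sage and fkh served as naming markers.

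**Figure D4:**
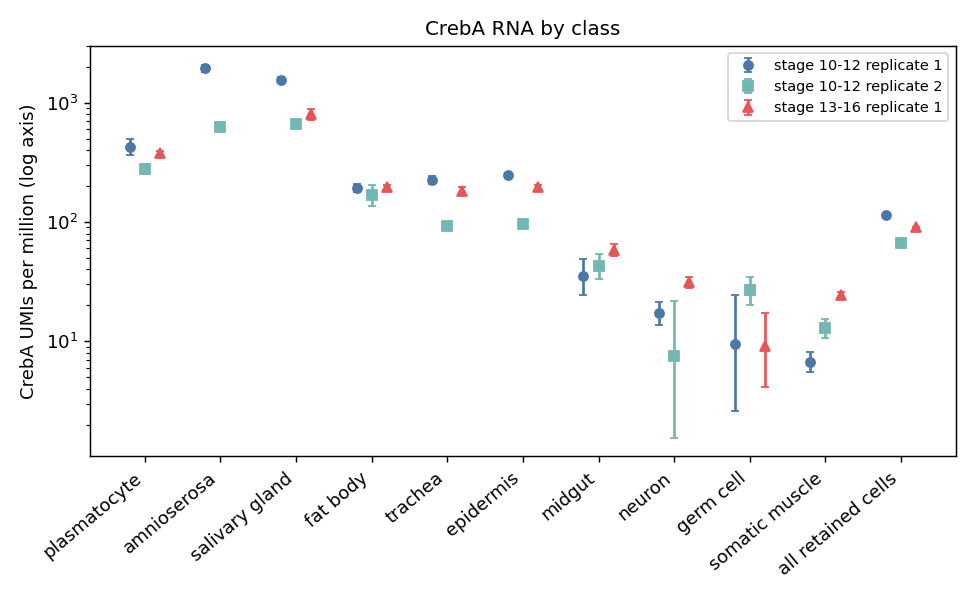
CrebA RNA in CPM (log axis) by class in each library, with exact Poisson intervals of 95% that cover counting error only. Salivary gland-like cells stood at 798 CPM at stage 13-16 and somatic muscle-like cells at 24.4 CPM.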

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

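No paired analysis was possible because the stages share only 1 replicate number. Keeping doublets changes nothing, since the automatic call marked none. Alternatives with UMI floors, likely doublets left out and low-depth clusters named too, and resolution 3 within classes, were chosen after seeing the data. The machinery set kept its call under every alternative tested with the preset correlation in plasmatocyte-like (0.79 to 0.96), fat body-like (0.32 to 0.63), salivary gland-like (0.15 to 0.41), trachea-like (0.16 to 0.32) and amnioserosa-like cells (0.04 to 0.73), and between stages in somatic muscle-like cells (-0.26 to -0.18). With an estimated correlation the set was called in 0 of the 10 classes against the remainder (smallest adjusted p = 0.718 with an estimated correlation), and the call between stages in somatic muscle-like cells was lost too. The few residual degrees of freedom of that setting allowed almost no call. Counts of higher machinery genes ranged from 24 to 82 in plasmatocyte-like, 0 to 52 in fat body-like, 6 to 25 in midgut-like, 1 to 17 in salivary gland-like and 0 to 29 in trachea-like cells; the lowest in plasmatocyte-like and fat body-like cells came without the library block. The cause of the changes below was not tested.

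With an estimated correlation, the whole-embryo lists N-glycosylation (-0.29), COPI and retrieval (-0.42), basement membrane (1.44), cuticle (2.41), cell cycle (-1.85), neuronal function (2.90), muscle contraction (3.22) and early patterning (-1.29) lost their calls. Genes higher at stage 13-16 numbered 51 with no count filter and 1174 by DESeq2, with 237 lower. With the stricter cell filter the medians were 0.0620 for ER folding and 0.81 for heat shock genes, now called, and CrebA stood at 0.0120 between stages. With likely doublets left out, ER translocation (-0.25) and heat shock (0.94) were called. Leaving out each stage 10-12 replicate gave -0.29 to 0.26 for CrebA, -0.15 to 0.00534 for ER folding, -0.16 to 0.0877 for COPII, -0.17 to 0.0910 for the machinery set in epidermis-like cells and -0.0409 to 0.28 in trachea-like cells.

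Between stages, the machinery set in trachea-like cells stood at -0.00384 with no count filter, -0.0567 at resolution 1 and -0.0324 above the UMI floors. In epidermis-like cells it stood at 0.0119 with RLE factors, 0.00197 above the UMI floors and -0.14, now called, with low-depth clusters named too. With no count filter, 1 machinery gene was higher in trachea-like and 1 in somatic muscle-like cells. Against the remainder, the set lost its call with equal weight per class in epidermis-like (0.0765) and midgut-like cells (0.0602), and with low-depth clusters named too in epidermis-like (0.12) and germ cell-like cells (-0.28). With likely doublets left out it was -0.0252 in midgut-like and -0.36 in germ cell-like cells. Leaving out each library gave -0.45 to -0.36 in germ cell-like cells, where the call ended without stage 10-12 replicate 1, and -0.10 to 0.0674 in somatic muscle-like cells, and -0.30 to 0.12 for Xbp1 in somatic muscle-like cells. In amnioserosa-like cells wbl was 1.69 at resolution 1, 0.92 with machinery genes used to cluster, 1.02 with the stricter filter, 0.73 above the UMI floors and 1.34 with likely doublets left out, and ERp60 was -0.0680 with the stricter filter and -0.0716 above the floors.

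Named cells made up 16.3%, 17.0% and 24.9% of cells in the 3 libraries at resolution 1; 16.0%, 17.7% and 24.3% with machinery genes used to cluster; 30.4%, 31.8% and 69.2% with the stricter filter; 50.6%, 37.8% and 66.3% above the UMI floors; and 25.2%, 29.8% and 44.5% with low-depth clusters named too. At resolution 3 they were 15.9% in stage 10-12 replicate 1 and 24.2% at stage 13-16, and with likely doublets left out 16.2% and 16.9% at stage 10-12.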

Other observations

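Glia-like cells, which were not among the classes tested, held machinery RNA at 2.22 ± 0.372% of UMIs at stage 10-12 (SD, n = 2) and 2.17% at stage 13-16. Their CrebA RNA stood at 273 ± 22.0 CPM and 142 CPM. Crystal cell-like cells, the other blood cell class, held 1.49 ± 0.667% and 0.752% of UMIs in the machinery, where plasmatocyte-like cells held 3.46 ± 1.12% and 3.02%. These shares rest on few cells: the library with fewest held 9 crystal cell-like, 22 glia-like and 15 plasmatocyte-like cells.

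Of the tests below, those of older embryos, of a shared batch, of doublets in plasmatocyte-like cells, of CrebA RNA against machinery RNA and of regrouped profiles were chosen after the results were seen.

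Stage 10-12 replicate 1 lies between replicate 2 and stage 13-16 for many genes. Over 4436 genes, the log2 ratio of replicate 1 to replicate 2 correlated with that of stage 13-16 to replicate 1 at r = 0.544. The shared replicate 1 alone would push r below 0. Older embryos in replicate 1 would give such a value. It restates the pattern, however, and does not tell that cause from others. A batch shift of the same size in replicate 1 and stage 13-16 cancels in the second ratio and would not give this value. A shift of unequal size would not cancel, so a shared batch stays open. On barcodes above the UMI floors alone r was 0.569, so the low-UMI barcodes do not account for it. Thinning the library totals left r at 0.546, but thinning sums leaves the ratios of well-counted genes as they are, so it tests nothing, and the difference in depth stays open.

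Genes of other tissues stood higher at stage 13-16 inside the trachea-like, epidermis-like and somatic muscle-like cells, by a median of 3.24 over 6 pairs of list and class, from 0.98 for neuronal genes in trachea-like cells to 3.67. edgeR called 0 genes in each class after adjustment over all genes tested, with 872, 1508 and 1450 at an unadjusted p under 0.05, and DESeq2 called 183, 575 and 337 higher and 42, 152 and 39 lower. No list kept its call with an estimated correlation (each adjusted p = 0.618 with an estimated correlation). Their difference in the classes exceeded that in the 10% of barcodes with fewest UMIs by a median of 0.31, from -0.14 to 1.43 over the pairs, so RNA free in the suspension may account for much of it. The prediction concerned the median, which lies within 1, while the script also asked for every pair to lie within 1, which 2 pairs did not; the question stays open. With likely doublets left out the median was 3.05, so those doublets do not account for it.

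The machinery share of plasmatocyte-like cells exceeded that of the 10% of barcodes with fewest UMIs by at least 1.38 percentage points in every library. If these barcodes stand for free RNA, such RNA would not give that excess. Whether they are debris or cells is not known, so free RNA is not excluded. Without Calr, Pdi, Arf1, Tapdelta and Hsc70-3, the 5 most abundant machinery genes, the share was at least 1.83 times that of the remainder. With likely doublets left out the median log2 fold change was 0.89. A few abundant genes and the likely doublets therefore do not account for the high share. Free RNA would not either, if the barcodes with fewest UMIs stand for it.

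Across named classes, more CrebA RNA went with more machinery RNA. Spearman's rho was 0.738, 0.482 and 0.787 over 20, 19 and 17 classes in stage 10-12 replicates 1 and 2 and stage 13-16 (adjusted p = 0.000510, 0.0383 and 0.000510 by random permutation of classes). Pearson's r was 0.708, 0.451 and 0.689, and 0.648, 0.683 and 0.681 without 2 classes each. Classes are not independent replicates, and the protein is absent, so the relation does not measure an action of CrebA.

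In each of 9 classes, regrouping the 6 profiles gave as many machinery genes past the threshold in 1 of 10 splits, the real one, with at most 0 in the others; 10 splits are too few for a share under 0.05.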
